A study of Homo sapiens with 12 samples.

How the data were processed

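RNA was sequenced from 2 human uveal melanoma cell lines, 92.1 and MP38, after 72 hours in DMSO, the solvent, or in VE-822 (berzosertib), an inhibitor of the kinase ATR. ATR is the kinase that responds to stalled replication forks. Each line and treatment had 3 libraries, 12 in all. The labels do not give the dose of VE-822; they state that it was chosen in each line to leave about 40% of the cells viable. Dose and cell line therefore cannot be separated. The labels do not say whether the 3 libraries of a group came from separate cultures. If they did not, the p-values measure only the spread between these samples, which may be technical. Libraries were made from poly(A)-selected RNA with a NEBNext Ultra II kit.

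Per the labels, the authors used cutadapt 4.8, FastQC 0.12.1, MultiQC 1.7, STAR 2.7.11a and featureCounts 2.0.6 on the GRCh38.p13 build, without stated parameters. The authors deposited 1 table of raw counts per gene for each cell line, with no normalization; features with no read in any of the 6 libraries of a table were absent from it. The deposited FPKM tables hold the same counts scaled for feature length and for the library's total, rounded to 3 decimals, and every value was checked against the count table within that rounding. Whether counting used strand is not stated, so values of overlapping and antisense genes are uncertain. Genes with near-identical copies are uncertain too, among them HSPA1A and HSPA1B, the histone genes, ribosomal protein genes, mitochondrial genes with nuclear copies, and ASNSP1, a pseudogene of ASNS.

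Total counts per library were 54415628 to 63638976 in MP38 and 112374503 to 137664800 in 92.1. Differential expression was computed from the counts in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, library sizes were scaled by TMM, and a quasi-likelihood F test compared VE-822 with DMSO in each line alone. A positive log2 fold change means higher in VE-822. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called when its adjusted p was under 0.05. The difference between lines was tested in 1 joint fit of all 12 libraries over features present in both tables, as the 92.1 response minus the MP38 response. That fit uses 1 spread per gene for both lines, although the spread between replicates differed between them. Within it 10682 genes were called in 92.1 and 9430 in MP38, against 9156 and 11194 in the fits of each line alone, which tested other sets of genes. Levels are given in CPM (counts scaled to a common library total) with TMM factors, as mean ± SD over n = 3 libraries. Fold changes are given with their standard error (SE), taken from the F statistic.

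26 gene lists were fixed before the data were examined, together with the tests, the rule for naming genes and the other settings to be tried. Each list was compared with all other genes by camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, and its p adjusted over the 26 lists. The same lists were also tested by camera with a correlation estimated from the data and by fry, which tests whether a list's genes move one way and does not compare them with other genes. Calls were lost with the estimated correlation even where it was below 0.01, as for the replication-dependent histones in MP38 (0.002). A call lost in that test therefore does not by itself show that the list's genes are correlated. Member counts use the threshold over all genes tested, and a second count uses p-values adjusted over the list alone. Genes named in the text follow a fixed rule. It takes, in each line, the 10 largest increases and 10 largest decreases among called protein-coding genes with a mean of at least 5 CPM and groups that do not overlap. It adds up to 4 called members of each list with the smallest adjusted p, and ATR, CHEK1, CDKN1A, MDM2, CCND1, MITF, PMEL, MKI67 and BAP1. For the difference between lines it takes the 5 largest and 5 smallest values among called genes with at least 5 CPM. That level is the mean over the 12 libraries of both lines, so a gene near 0 in 1 line can pass through the other. The text names a part of the genes so chosen. Genes listed for 1 control library of 92.1 were chosen after its values were seen.

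The fits were tested on simulated data with the libraries' own sizes. Each gene had 1 mean level and 1 spread, estimated from the data and shared by all libraries of a fit. In these data 50 genes each were changed by each of 4 factors up to 4 times. Of all genes changed 4 times, 90% were recovered in MP38, 92% in 92.1 and 72% in the difference between lines. A bar of 90% set for this check was missed by the difference between lines. The bar was then set on genes with at least 1 CPM, where 100% were recovered in all 3 fits; every miss had been below that level. Among genes with at least 1 CPM changed 1.5 times, 86.5% were recovered in MP38, 79.3% in 92.1 and 60% in the difference between lines. False calls were 11 of 153 in MP38, 5 of 106 in 92.1 and 2 of 86 in the difference between lines. In the simulated data changes of 1.5 times were therefore missed more often in 92.1 and in the difference between lines. No simulated library stood apart and few genes were changed, while in the real data 52.3%, 39.9% and 40.9% of genes were called. The false calls therefore do not show the rate in the real data.

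The other settings tried were RLE factors, library size only, DESeq2 1.42.0, limma-voom, no filter, a filter at 5 CPM, a minimum absolute log2 fold change of 1, an adjusted p of 0.01, the replicate number as a block, counts thinned to the lowest total, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), all 12 libraries in 1 fit, and leaving out each library in turn. The filter was applied anew when a library was left out, so the genes tested and the tested members of a list could change. A robust quasi-likelihood fit and protein-coding genes alone were added after seeing the data. No library or value column was left out of the comparisons reported.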

Results

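Poly(A) RNA was measured in 12 libraries from the uveal melanoma cell lines MP38 and 92.1, 3 per line and treatment, after 72 hours in DMSO or in the ATR inhibitor VE-822. In MP38, total counts per library were 61045071 to 63638976 in DMSO and 54415628 to 60891725 in VE-822. In 92.1 they were 112374503 to 123705501 in DMSO and 113370680 to 137664800 in VE-822. Within each line the first principal component parted VE-822 from DMSO and held 64.7% of the variance in MP38 and 69.8% in 92.1. In 92.1 the second component, 13.6% of the variance, set DMSO library 3 apart from the other 5 libraries. Replicates differed by more than counting noise, with a chi-square per gene of 2.30 to 7.45 between replicates of a group, except that DMSO library 3 of 92.1 differed from DMSO libraries 1 and 2 by 82.0 and 82.6. The comparisons ask which transcripts change in each line when ATR is inhibited, and whether the lines respond alike.

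In MP38, genes of mitosis were higher in VE-822 than in DMSO. The kinetochore motor CENPE rose from 25.4 ± 0.745 to 94.6 ± 1.67 CPM (SD, n = 3 in each group, as for all CPM values), a log2 fold change of 1.90 ± 0.0407 (SE). The proliferation marker MKI67 rose from 111 ± 2.98 to 253 ± 3.46 CPM. The cell cycle inhibitor CDKN1A, a p53 target, rose from 10.4 ± 0.743 to 44.1 ± 7.39 CPM. GLDC, which breaks down glycine, fell from 50.6 ± 0.961 to 5.99 ± 0.506 CPM. In all, 5750 of 21415 genes tested were higher and 5444 lower in VE-822 (edgeR), of which 979 and 523 changed by at least 1 on the log2 scale.

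All 36 members of the mitosis list were higher in MP38, with a median log2 fold change of 1.26 (36 adjusted over the list alone). The camera adjusted p was 1.08e-32, and the adjusted p was 0.00489 with an estimated correlation. The spindle protein HMMR rose by 1.88 ± 0.0479 (log2, SE), the cytokinesis kinesin KIF20A by 1.78 ± 0.0457 and the spindle checkpoint kinase BUB1 by 1.74 ± 0.0451. The DNA replication and E2F target list, in contrast, had 14 members higher, 15 lower and 13 not past the threshold (14 and 15 adjusted over the list alone; camera adjusted p = 0.959). Thymidine kinase TK1 rose by 1.32 ± 0.0415, while the helicase subunit MCM2 had a log2 fold change of -0.61 ± 0.0410. The median of this list was 0.0006 and its mean 0.03, while the camera test pointed down. The homologous recombination and Fanconi anaemia list had 10 members higher, 8 lower and 12 not past the threshold (10 and 8 adjusted over the list alone; camera adjusted p = 0.937; median -0.01, mean 0.03, test up). BRCA1 rose from 44.0 ± 1.12 to 56.7 ± 2.69 CPM and BRCA2 from 15.4 ± 0.516 to 22.3 ± 1.35 CPM. The ATR checkpoint list had 9 members higher, 4 lower and 8 not past the threshold (11 and 4 adjusted over the list alone; camera adjusted p = 0.0964). ATR fell from 54.5 ± 0.346 to 44.6 ± 2.36 CPM, and CHEK1, the kinase that ATR activates, rose from 16.1 ± 0.506 to 20.7 ± 0.880 CPM. PKMYT1, an inhibitory kinase of CDK1, rose from 16.7 ± 0.464 to 23.6 ± 0.547 CPM.

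In the p53 target list, 13 members were higher, 7 lower and 8 not past the threshold in MP38 (14 and 7 adjusted over the list alone; camera adjusted p = 0.185). CDKN1A rose by 2.09 ± 0.0876 (log2, SE), the growth arrest gene GADD45A by 2.08 ± 0.0840 and the secreted factor GDF15 by 1.56 ± 0.0948. MDM2, the ubiquitin ligase of p53, rose by 0.25 ± 0.0413, and the kinase PLK2 had a log2 fold change of -0.77 ± 0.0375. Of the replication-dependent histones, most of whose transcripts lack a poly(A) tail, 11 were higher, 1 lower and 4 not past the threshold (12 and 1 adjusted over the list alone). Camera gave an adjusted p = 0.00891, and an adjusted p = 0.147 with an estimated correlation. H1-2 rose from 9.40 ± 0.387 to 30.1 ± 1.12 CPM and H2AC6 from 18.5 ± 2.06 to 26.0 ± 0.925 CPM. The call of this list was lost among genes of at least 5 CPM (adjusted p = 0.561). The share of ribosomal RNA in counts, mitochondrial included, was 0.963% ± 0.0124 in DMSO and 1.27% ± 0.0427 in VE-822 (exact permutation test, two-sided p = 0.1, the smallest possible here).

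Cholesterol biosynthesis genes rose together in MP38, with 20 of 21 members higher and 1 lower (20 and 1 adjusted over the list alone). The list's camera adjusted p was 2.01e-11, and 0.032 with an estimated correlation. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose by 1.75 ± 0.0468 (log2, SE). Of the lysosome and autophagy genes, 18 were higher, 2 lower and 1 not past the threshold (19 and 2 adjusted over the list alone). Its adjusted p by camera was 1.62e-07, and 0.131 with an estimated correlation. The lysosomal galactosidase GLA rose from 25.5 ± 0.165 to 42.4 ± 0.336 CPM. The MAPK output list had 15 members higher, 2 lower and 3 not past the threshold (15 and 2 adjusted over the list alone). The camera adjusted p was 3.33e-06, and the adjusted p was 0.131 with an estimated correlation. The AP-1 subunit FOSL1 rose from 52.9 ± 3.70 to 181 ± 26.9 CPM, and EGR1, an immediate early transcription factor, from 55.4 ± 11.3 to 135 ± 14.5 CPM. CCND1 was 468 ± 9.19 and 491 ± 14.1 CPM, which did not pass the test (adjusted p = 0.145). The hypoxia and glycolysis list had 13 members higher, 2 lower and 4 not past the threshold (13 and 2 adjusted over the list alone; camera adjusted p = 0.000351, and adjusted p = 0.131 with an estimated correlation), with the glycolytic enzyme PGAM1 up by 0.59 ± 0.0364.

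Of the melanocyte lineage and pigmentation genes, 13 were higher, 5 lower and 3 not past the threshold in MP38 (13 and 6 adjusted over the list alone). Camera gave an adjusted p = 0.000784, and an adjusted p = 0.307 with an estimated correlation. The melanocyte channel TRPM1 rose from 4.21 ± 0.233 to 22.5 ± 1.33 CPM, the melanosome enzyme TYRP1 from 29.0 ± 2.40 to 79.7 ± 3.40 CPM, MLANA from 154 ± 11.8 to 380 ± 1.76 CPM and the melanosome matrix protein PMEL from 1966 ± 33.9 to 3054 ± 29.1 CPM. MITF, the lineage's transcription factor, went the other way, from 172 ± 11.6 to 144 ± 16.7 CPM. Its log2 fold change of -0.26 was -0.17 without VE-822 library 3, and its call was lost in a robust fit chosen after seeing the data (adjusted p = 0.0671) and with log2(FPKM + 1) and no filter (adjusted p = 0.12). Of the 4 tested markers of class 2 uveal melanoma, the class of high metastatic risk, 3 were higher and 1 did not pass the threshold (4 higher adjusted over the list alone). The list's camera adjusted p was 0.0079, and 0.147 with an estimated correlation. The secreted protein ECM1 rose from 19.8 ± 0.453 to 99.7 ± 3.83 CPM. The list's call was lost among genes of at least 5 CPM (adjusted p = 0.0682). The tumour suppressor BAP1 was 142 ± 5.65 and 137 ± 5.50 CPM (adjusted p = 0.315).

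Cytosolic ribosomal protein genes fell in MP38, with 29 of 32 lower and 3 not past the threshold (29 lower and 1 higher adjusted over the list alone; median -0.35). Its adjusted p by camera was 3.73e-12, and 0.406 with an estimated correlation. RPLP0 fell from 3246 ± 103 to 2053 ± 167 CPM. The heat shock list had 8 members lower, 3 higher and 1 not past the threshold (8 and 3 adjusted over the list alone). The camera adjusted p was 0.0498, and the adjusted p was 0.243 with an estimated correlation. The constitutive chaperone HSPA8 fell from 2381 ± 21.2 to 1061 ± 21.7 CPM and the inducible HSPA1A from 56.4 ± 0.930 to 29.4 ± 1.89 CPM, while the small chaperone CRYAB rose from 109 ± 2.59 to 198 ± 2.67 CPM. The call of the heat shock list was lost with RLE factors (adjusted p = 0.0513), among genes of at least 5 CPM (adjusted p = 0.14) and without DMSO library 1 (adjusted p = 0.0532). Of the 13 mitochondrially encoded genes, 10 were higher, 1 lower and 2 not past the threshold (10 and 1 adjusted over the list alone). Camera gave an adjusted p = 0.00118, and an adjusted p = 0.491 with an estimated correlation. The mitochondrial share of counts was 7.02% ± 0.223 in DMSO and 8.59% ± 0.0997 in VE-822 (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). MT-CO1, a subunit of cytochrome oxidase, rose by 0.61 ± 0.0461; with log2(FPKM + 1) and no filter its call was lost (adjusted p = 0.0953). The type I interferon list had 18 members higher, 3 lower and 13 not past the threshold (19 and 3 adjusted over the list alone). The list's camera adjusted p was 0.00347, and 0.406 with an estimated correlation. OAS2, an antiviral enzyme, rose from 9.59 ± 0.460 to 22.1 ± 3.23 CPM.

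The largest increases in MP38 among protein-coding genes of at least 5 CPM were in SPRR2D, a cornified envelope protein (log2 fold change 3.49 ± 0.1004), the thioredoxin inhibitor TXNIP (3.46 ± 0.106), KCP (3.11 ± 0.0870), PRDM7 (3.02 ± 0.0751), the cytokine IL24 (2.76 ± 0.0894) and ARRDC4, a relative of TXNIP (2.48 ± 0.0536). TXNIP rose from 20.6 ± 5.84 to 227 ± 2.27 CPM. The largest decreases were in GLDC (-3.08 ± 0.0577), IGFBP5 (-2.56 ± 0.0682), the ephrin receptor EPHB3 (-2.28 ± 0.0664), SERPINA3 (-2.12 ± 0.0941) and the sulfate transporter SLC26A2 (-1.97 ± 0.0487). The gelatinase MMP2 fell from 147 ± 8.88 to 43.6 ± 3.79 CPM. Scaled by library size only, 5085 genes of MP38 were higher and 6070 lower, so the balance of higher and lower calls turned with the scaling.

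In 92.1, p53 targets were higher and genes of DNA replication and mitosis lower in VE-822, list calls that were lost with an estimated correlation (adjusted p = 0.185 to 0.206). CDKN1A rose from 18.4 ± 2.23 to 511 ± 52.4 CPM and MDM2 from 70.3 ± 6.34 to 195 ± 8.69 CPM. MKI67 fell from 284 ± 18.9 to 60.4 ± 8.15 CPM, CHEK1 from 41.8 ± 4.61 to 11.4 ± 1.19 CPM and the replication licensing factor CDT1 from 84.8 ± 1.28 to 18.2 ± 1.80 CPM. ATR itself was 47.3 ± 2.91 CPM in DMSO and 45.3 ± 0.363 in VE-822, which did not pass the test (adjusted p = 0.421). Of 22943 genes tested, 4658 were higher and 4498 lower, of which 1759 and 737 changed by at least 1 on the log2 scale. Without DMSO library 3, which stood apart from the other DMSO libraries, 6377 were higher and 6899 lower.

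Of the p53 targets, 26 of 28 tested were higher in 92.1, none was lower and 2 did not pass the threshold (26 adjusted over the list alone; median 1.41). Its adjusted p by camera was 7.15e-20, and 0.185 with an estimated correlation. The death receptor family member EDA2R rose from 9.78 ± 0.400 to 50.8 ± 0.773 CPM, the antiproliferative gene BTG2 from 8.61 ± 0.552 to 43.6 ± 3.43 CPM and the mitochondrial reductase FDXR from 18.6 ± 0.546 to 60.2 ± 2.04 CPM. All 36 mitosis genes were lower, with a median of -1.92 (36 adjusted over the list alone). The camera adjusted p was 2.39e-33, and the adjusted p was 0.185 with an estimated correlation. KIF20A fell from 65.6 ± 3.70 to 17.5 ± 0.989 CPM, the cyclin CCNA2 from 161 ± 2.18 to 40.8 ± 3.75 CPM and the cytokinesis kinesin KIF23 from 115 ± 0.443 to 35.3 ± 2.18 CPM. In the DNA replication and E2F target list 41 of 42 members were lower and 1 did not pass the threshold (42 adjusted over the list alone; median -1.72). Camera gave an adjusted p = 1.04e-28, and an adjusted p = 0.206 with an estimated correlation. The primase subunit PRIM1 fell from 48.0 ± 1.90 to 11.1 ± 0.532 CPM and the clamp loader subunit RFC3 from 113 ± 3.76 to 29.7 ± 2.12 CPM.

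The homologous recombination and Fanconi anaemia list had 29 members lower in 92.1 and 1 not past the threshold (29 adjusted over the list alone; median -1.49). The list's camera adjusted p was 4.42e-21, and 0.185 with an estimated correlation. FANCD2 fell from 59.97 ± 3.64 to 13.5 ± 0.402 CPM, BRCA1 from 76.7 ± 5.29 to 18.9 ± 1.71 CPM and BRCA2 from 48.3 ± 2.32 to 11.03 ± 1.23 CPM. In the ATR checkpoint list 16 members were lower and 5 not past the threshold (18 lower adjusted over the list alone). Its adjusted p by camera was 2.39e-11, and 0.206 with an estimated correlation. The mitotic entry kinases WEE1 and PKMYT1 had log2 fold changes of -1.51 ± 0.0528 and -2.12 ± 0.103, and TOPBP1, an activator of ATR, of -1.24 ± 0.0665. Replication-dependent histones were higher, with 12 of 14 tested past the threshold, 1 lower and 1 not past it (12 and 1 adjusted over the list alone; median 2.39). The camera adjusted p was 5.11e-07, and the adjusted p was 0.206 with an estimated correlation. H2AC6 rose from 1.93 ± 0.401 to 27.3 ± 2.42 CPM and H2BC12 from 6.91 ± 0.233 to 38.0 ± 5.63 CPM. Most transcripts of these histones lack a poly(A) tail, so poly(A)-selected libraries do not show whether their RNA as a whole rose. Cytosolic ribosomal protein genes had 20 members higher and 12 not past the threshold (23 higher adjusted over the list alone; median 0.19; camera adjusted p = 5.57e-07, and adjusted p = 0.464 with an estimated correlation), with RPS19 up by 0.49 ± 0.0594. The YAP/TAZ target list had 10 members higher, 3 lower and 5 not past the threshold (11 and 3 adjusted over the list alone). Camera gave an adjusted p = 0.00624, and an adjusted p = 0.185 with an estimated correlation. The matricellular protein CCN1 rose from 13.7 ± 0.429 to 36.0 ± 1.03 CPM and the nucleotidase NT5E from 7.57 ± 1.51 to 20.7 ± 1.69 CPM.

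**Figure D1:**
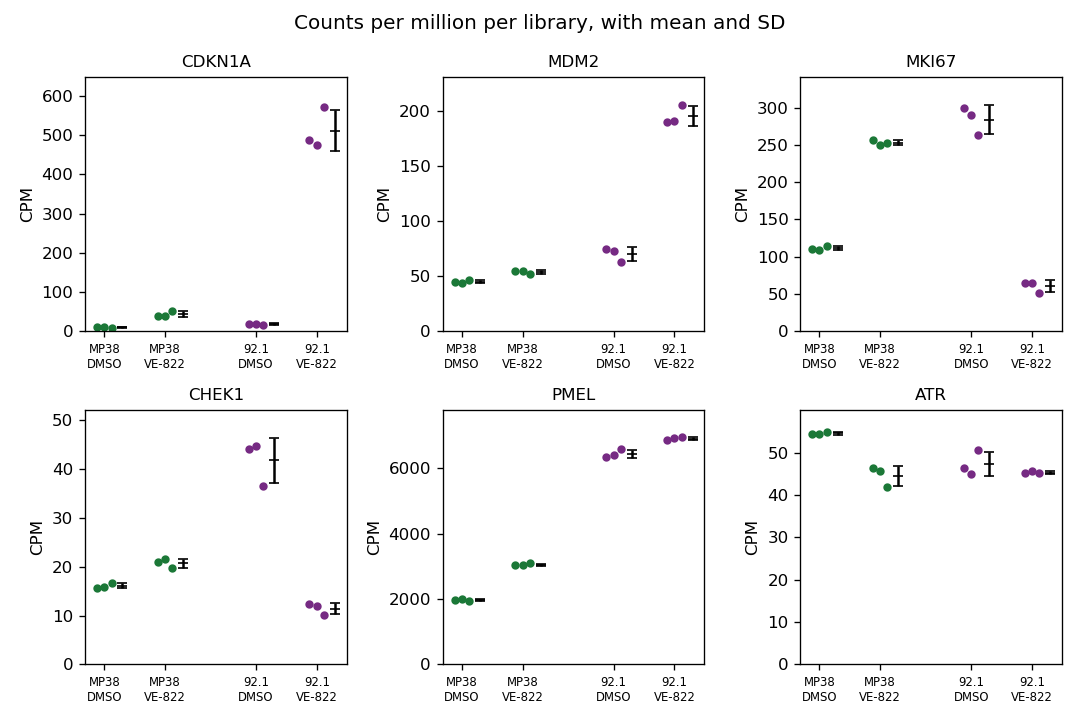
CPM of 6 genes in each of the 12 libraries (points), with the mean and SD of each group of 3 (black bars), by cell line and treatment. CDKN1A rose in both lines, while MKI67 was higher in VE-822 in MP38 (111 to 253 CPM) and lower in 92.1 (284 to 60.4 CPM).

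The largest increases in 92.1 among protein-coding genes of at least 5 CPM were in the inducible chaperone HSPA6, from 0.215 ± 0.0708 to 10.7 ± 4.26 CPM, and CDKN1A. H2AC6, H2BC21 and H2BC5 followed, with log2 fold changes of 3.82 ± 0.142, 3.54 ± 0.1599 and 3.44 ± 0.178. The vault protein MVP rose from 1.61 ± 0.136 to 12.5 ± 0.253 CPM and EGR1 from 7.10 ± 0.573 to 52.4 ± 24.7 CPM. The cystine transporter SLC7A11 and the asparagine synthetase ASNS had the lowest fitted values, -3.83 ± 1.11 and -3.31 ± 1.04, but their size rested on DMSO library 3. Without it they were -1.02 and -0.75, smaller but still called (adjusted p = 1.28e-10 and 0.000486). Both lost their call when any VE-822 library was left out, the adjusted p of SLC7A11 then being 0.0762 to 0.0938 and that of ASNS 0.0947 to 0.11. The values were then -3.87 to -3.79 for SLC7A11 and -3.41 to -3.22 for ASNS. Next came the transcription factor E2F2 (-2.83 ± 0.139), the centromere protein CENPU (-2.50 ± 0.0936), the phosphatase CDC25C (-2.47 ± 0.114), the exonuclease EXO1 (-2.46 ± 0.153), the kinetochore protein SPC25 (-2.44 ± 0.117) and the centriole kinase PLK4 (-2.39 ± 0.112).

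The melanocyte list had 5 members higher, 3 lower and 14 not past the threshold in 92.1 (5 and 3 adjusted over the list alone; camera adjusted p = 0.704). MITF fell from 454 ± 10.3 to 339 ± 16.8 CPM and the pigment enzyme DCT from 12.5 ± 0.283 to 4.19 ± 0.590 CPM. PMEL was 6444 ± 127 and 6902 ± 45.6 CPM, which did not pass the test (adjusted p = 0.144) but did so without DMSO library 3 (adjusted p = 0.0276), with library size only (adjusted p = 0.0155) and in 5 other settings. BAP1 fell from 108 ± 4.59 to 94.3 ± 0.952 CPM, a call lost with library size only (adjusted p = 0.0647), without VE-822 library 2 (adjusted p = 0.0628) and in the FPKM settings (adjusted p = 0.0584 to 0.0949). CCND1 was 444 ± 14.6 and 420 ± 11.9 CPM (adjusted p = 0.222, and 0.0191 without DMSO library 3). The MAPK output list had 8 members higher, 7 lower and 5 not past the threshold (8 and 8 adjusted over the list alone; camera adjusted p = 0.963; median 0.03, mean 0.19, test down). Of the cholesterol biosynthesis genes 1 was higher and 19 did not pass the threshold (1 adjusted over the list alone; camera adjusted p = 0.963); without DMSO library 3 this list was called lower, with a mean of -0.25 (adjusted p = 4.39e-06 with the preset correlation; the estimated one was not run without that library, and with all libraries it was 0.796, with an adjusted p = 0.987). The integrated stress and unfolded protein list, whose genes set DMSO library 3 apart, had 3 members higher, 6 lower and 13 not past the threshold (3 and 6 adjusted over the list alone; camera adjusted p = 0.242).

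Further lists did not pass the camera test in 92.1 with all libraries and the default filter. The heat shock list had 2 members higher, 5 lower and 5 not past the threshold (2 and 5 adjusted over the list alone; camera adjusted p = 0.376; median -0.18, mean 0.23, test down). In it CRYAB rose from 3.25 ± 0.751 to 15.9 ± 1.73 CPM and HSPA1A from 1.57 ± 0.579 to 7.51 ± 2.00 CPM. HSPA1B, a near-identical copy of HSPA1A, held more counts and changed less. It was 43.1 CPM in the mean of DMSO libraries 1 and 2, 19.4 in DMSO library 3 and 55.9 in the VE-822 mean. The lysosome and autophagy list had 10 members higher, 2 lower and 9 not past the threshold (11 and 2 adjusted over the list alone; camera adjusted p = 0.0563), GLA falling from 54.5 ± 7.24 to 36.9 ± 0.852 CPM. The hypoxia and glycolysis list had 3 members higher, 6 lower and 8 not past the threshold (3 and 6 adjusted over the list alone; camera adjusted p = 0.145). Of the class 2 markers 2 were higher and 2 not past the threshold (2 adjusted over the list alone; camera adjusted p = 0.172), ECM1 rising from 1.11 ± 0.0551 to 3.27 ± 0.896 CPM. Without DMSO library 3 these 4 lists passed the test with the preset correlation. The lysosome list (mean 0.14, adjusted p = 0.0187) and the class 2 markers (mean 0.73, against 0.43 with all libraries, adjusted p = 0.0337) pointed up. Heat shock (adjusted p = 0.0187) and hypoxia (adjusted p = 0.0337) pointed down relative to other genes, although their means were 0.06 and 0.01. With all libraries and an estimated correlation the 4 had adjusted p = 0.274 to 0.865. The lysosome list also passed it among genes of at least 5 CPM (adjusted p = 0.00782). Of the MHC class I genes, 7 were higher, 2 lower and 8 not past the threshold (8 and 3 adjusted over the list alone; camera adjusted p = 0.0563), with the peptide transporter TAP1 up from 4.70 ± 0.299 to 16.3 ± 0.853 CPM and HLA-B from 32.1 ± 1.62 to 70.7 ± 2.48 CPM. This list passed the test without DMSO library 1 (adjusted p = 0.0384), without VE-822 library 2 (adjusted p = 0.0481) and among genes of at least 5 CPM (adjusted p = 0.0488). With all libraries and an estimated correlation the MHC class I list had an adjusted p = 0.206. Scaled by library size only, 5684 genes of 92.1 were higher and 3534 lower, 61.7% higher against 50.9% with TMM; with RLE factors 4383 were higher and 4774 lower, 47.9%.

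The responses of the 2 lines differed in the joint fit. CENPE had a log2 response of 1.91 in MP38 and -2.01 in 92.1, a difference of -3.92 ± 0.112 (SE; adjusted p = 6.64e-13), and KIF20A differed by -3.65 ± 0.0831 and MKI67 by -3.39 ± 0.113. CDKN1A rose in both lines and by 2.74 ± 0.158 more in 92.1 (adjusted p = 1.63e-09), and MDM2 by 1.252 ± 0.0877 more. BRCA2, PKMYT1, BRCA1 and CHEK1 had responses lower in 92.1 by -2.63 ± 0.111, -2.59 ± 0.1197, -2.35 ± 0.0983 and -2.20 ± 0.124. Of 24958 genes tested, the response was more positive in 92.1 for 5510 and more positive in MP38 for 4704, 53.9%. The balance turned with the scaling: with RLE factors these were 4984 and 5175, 49.1%, and with library size only 6455 and 3950, 62.0%. The median over all genes was 0.11, or 0.07 with RLE factors and 0.19 with library size only.

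Of the 26 lists, 3 were called more positive in 92.1 and 9 more positive in MP38. With an estimated correlation, p53 targets (adjusted p = 0.0174), mitosis (adjusted p = 0.0174) and the melanocyte list (adjusted p = 0.0443) held. The p53 target list had a median difference of 1.24, with 23 members more positive in 92.1, 1 more positive in MP38 and 4 not past the threshold (24 and 1 adjusted over the list alone; camera adjusted p = 2.01e-14). In the mitosis list all 36 were more positive in MP38, with a median of -3.19 (36 adjusted over the list alone; camera adjusted p = 6.42e-49). In the melanocyte list 13 were more positive in MP38, 4 more positive in 92.1 and 5 not past the threshold (14 and 4 adjusted over the list alone; median -0.45; camera adjusted p = 8.32e-06). PMEL differed by -0.51 ± 0.0461. The other called lists lost the call with an estimated correlation. They were DNA replication and E2F targets (41 of 42 more positive in MP38, 41 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation), homologous recombination (27 of 30, 27 adjusted over the list alone; adjusted p = 0.0978 with an estimated correlation) and the ATR checkpoint (16 of 21 more positive in MP38 and 1 in 92.1, 17 and 1 adjusted over the list alone; adjusted p = 0.146 with an estimated correlation). Ribosomal protein genes were more positive in 92.1 (31 of 32, 31 adjusted over the list alone; adjusted p = 0.253 with an estimated correlation), as were histones (10 of 17, 1 opposite, 11 and 1 adjusted over the list alone; adjusted p = 0.253 with an estimated correlation).

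**Figure D2:**
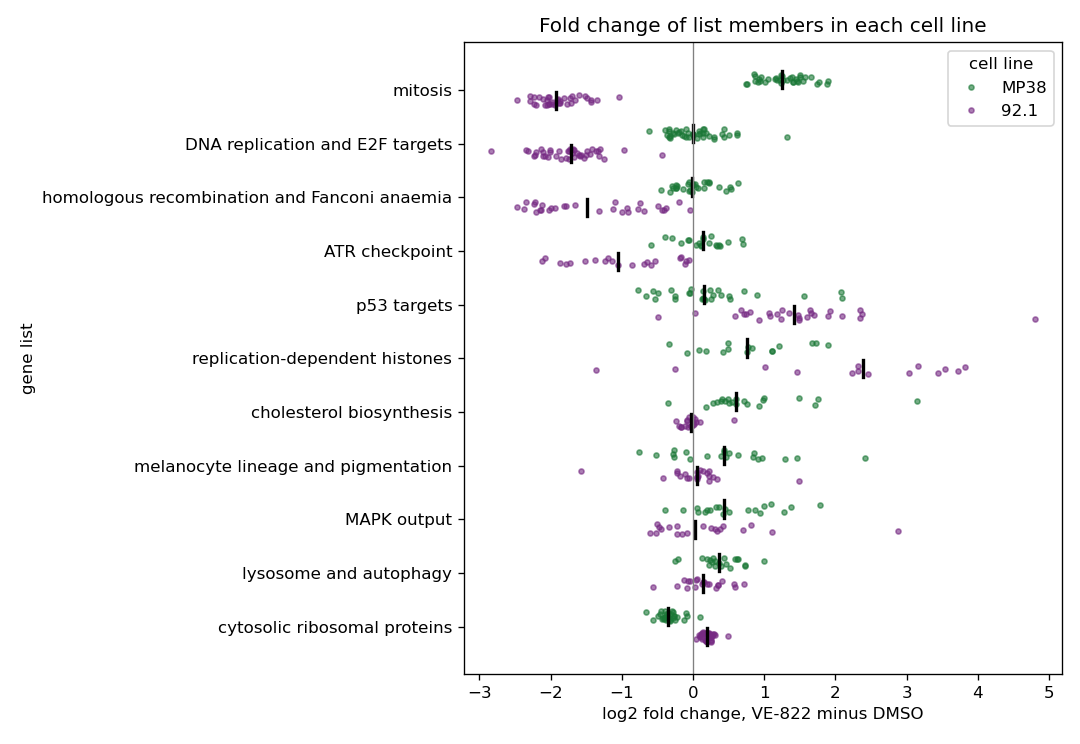
Log2 fold change, VE-822 minus DMSO, of each tested member (points) of 11 gene lists in MP38 and 92.1, with the median of each list (black bar). The mitosis medians lay at 1.26 in MP38 and -1.92 in 92.1, and the p53 target median was 1.41 in 92.1.

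Cholesterol biosynthesis genes were more positive in MP38 (12 of 21, 13 adjusted over the list alone; adjusted p = 0.465 with an estimated correlation), as were the hypoxia list (9 of 19, 3 opposite, 10 and 3 adjusted over the list alone; adjusted p = 0.0722 with an estimated correlation), the MAPK output list (10 of 20, 2 opposite, 11 and 2 adjusted over the list alone; adjusted p = 0.235 with an estimated correlation) and the lysosome list (8 of 21, 2 opposite, 8 and 3 adjusted over the list alone; adjusted p = 0.235 with an estimated correlation, and 0.0534 with the replicate number as a block). GLA differed by -1.26 ± 0.105, with a log2 response of 0.74 in MP38 and -0.52 in 92.1. ATR differed by 0.26 ± 0.0735 (adjusted p = 0.0106), a call lost without any 1 of MP38 DMSO libraries 1 to 3, MP38 VE-822 library 3 and 92.1 VE-822 libraries 1 to 3 (adjusted p = 0.0505 to 0.105). MITF (adjusted p = 0.336), CCND1 (adjusted p = 0.119), BAP1 (adjusted p = 0.21) and CCN1 (adjusted p = 0.748) did not pass the test of the difference, with values of -0.13, -0.12, -0.11 and -0.04. MITF passed it without VE-822 library 3 of MP38 (adjusted p = 0.014), BAP1 without DMSO library 3 of 92.1 (adjusted p = 0.00522), and CCND1 with RLE factors (adjusted p = 0.0431), with DESeq2 (adjusted p = 0.0184) or without 1 of 3 libraries (adjusted p = 0.0147 to 0.0354).

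The most positive differences among genes with a mean of at least 5 CPM over all 12 libraries began with HSPA6. It lies on chromosome 1 from 161524540 to 161526894 (GRCh38, ENSG00000173110.8). Its log2 response was -1.74 in MP38 and 5.68 in 92.1, a difference of 7.42 ± 0.354. MMP2, SHANK2, CHL1 and MAP9 followed, but none of these had a count in the 3 DMSO libraries of 92.1. Against a floor of 3 counts over the DMSO group, scaled for library totals, their 21, 19, 23 and 20 counts in VE-822 were 6.43, 5.82, 7.05 and 6.13 times higher. These folds do not allow for chance in the VE-822 counts and are not lower bounds. The most negative difference was that of TXNIP, on chromosome 1 from 145992435 to 145996579 (ENSG00000265972.6), at -5.14 ± 0.458, with responses of 3.47 in MP38 and -1.67 in 92.1, and -4.46 without DMSO library 3 of 92.1. LMX1B had no count in the DMSO libraries of MP38 and 7 in VE-822, 2.51 times the same floor and likewise no lower bound. Its call was lost without VE-822 library 3 of MP38 (adjusted p = 0.0525). Its difference of -4.67 turned positive on FPKM, at 0.14 with log2(FPKM + 1) (adjusted p = 0.0383) and 0.11 with log2(FPKM + 0.1) (adjusted p = 0.414). ASNSP1 and SLC7A11 depended on DMSO library 3 of 92.1, without which their differences were 1.05 (adjusted p = 0.55) and -1.001 (adjusted p = 5.88e-10) in place of -4.83 and -3.79. The call of ASNSP1 was also lost without any 1 VE-822 library of 92.1 (adjusted p = 0.0508 to 0.0602). In 92.1 its mean level was 0.350 CPM in DMSO and 0.0138 CPM in VE-822.

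Across the 19146 genes tested in both lines, the fold changes had a Pearson r of 0.0148 and a Spearman rho of -0.0424. This correlation is across genes, which are not independent replicates. It was 0.136 with no filter and -0.149 among genes of at least 5 CPM. Of the 5025 genes called in both lines, 2296 (45.7%) changed in the same direction and 2729 in opposite directions. If calls in MP38 and 92.1 were independent over the 19146 genes, 2177.6 and 2181.1 would be met. Both observed counts lay above these values. The values therefore do not show whether directions agreed more or less often than by chance. The 1592 genes higher in MP38 and lower in 92.1, against 1161.4 if independent, made up most of the excess in opposite directions.

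**Figure D3:**
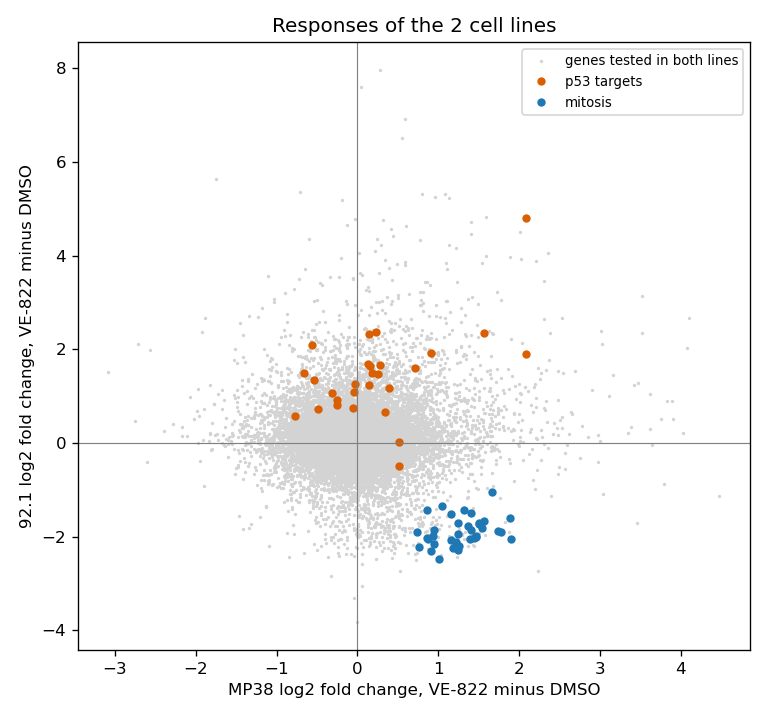
Log2 fold change (VE-822 minus DMSO) in 92.1 against MP38 for the 19146 genes tested in both lines (grey), with p53 targets (orange) and mitosis genes (blue). The 36 mitosis genes lay in the quadrant higher in MP38 and lower in 92.1, and the correlation across all genes was 0.0148.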

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

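The tests of library scaling, swapped labels, the p53 response, mixed RNA, the stress response and sequencing depth were chosen after the results were seen. The splits of the libraries and the test for genomic DNA were fixed before theirs.

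The 3 counts of genes past the threshold were compared with other splits of the same libraries. In each line only 10 splits of 3 against 3 exist, too few for a share under 0.05. The real split gave 11194 genes in MP38 and 9156 in 92.1 (edgeR), and the highest other gave 0 in each line. For the difference between lines, 1 of 100 drawn splits, the real one, gave as many genes (10214, against 3111 for the highest other). The other splits mix DMSO and VE-822 libraries, so the treatment effect adds to their spread and lowers their counts. They do not show what lines with equal responses would give, so this comparison does not exclude chance.

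The first pattern is that the mitosis list was higher in MP38 and lower in 92.1 and that a test of the difference between lines passed its threshold (median -3.19, adjusted p = 6.42e-49, and 0.0174 with an estimated correlation, with which the list was called in MP38, at 0.00489, and not in 92.1, at 0.185). The choice among TMM, RLE and library size only does not account for it. Under these the median stayed at 1.22 to 1.26 in MP38 and at -1.95 to -1.85 in 92.1, the smallest absolute value being 1.22. These scalings differed little, with TMM factors of 0.962 to 1.042, so they could not have turned the sign. The test therefore does not exclude other errors of scaling between libraries. Swapped DMSO and VE-822 labels in 1 line cannot be told apart from a real difference, as the p53 targets do not decide it. Of the 18 p53 targets called in both lines, 11 or 61.1% changed in the same direction (exact binomial test, two-sided p = 0.481). That test takes the genes as independent, which they need not be. The p53 target list was also mixed in MP38 itself, with 13 members higher and 7 lower. A stronger p53 target response in 92.1 (adjusted p = 0.0174 with an estimated correlation) cannot be told apart from other differences between the lines, since that value does not test whether mitosis genes follow it, and in MP38 CDKN1A rose too (log2 2.09) while all 36 mitosis genes rose. The dose, chosen separately in each line and not given, and other differences between the lines stay open and untested.

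The second pattern is that DMSO library 3 of 92.1 stood apart, with 87 genes higher and 9 lower by at least 2 times than the mean of DMSO libraries 1 and 2 at 5 CPM or more, led by DDIT4 (104 against 3.80 CPM), SLC7A11 (253 against 12.97 CPM) and ASNS (35.2 against 2.20 CPM). The tables argue against VE-822 RNA mixed into it, since 78 of these 96 genes, or 81.3%, lay over 1.5 times outside the span between the other DMSO libraries and VE-822. They argue against MP38 RNA as well: 40 genes abundant in MP38 reached 0.0189% of their MP38 level. The integrated stress list had a median log2 of 1.47 there against DMSO libraries 1 and 2, with 16 of 22 genes above both, but it was tested because its genes had been seen among those higher, so a stress response as the cause stays open. A library from another culture under this label was not tested, and the design names no group that gives a biological explanation.

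The third pattern is a gain of genes at low levels in VE-822 in 92.1: 12406 autosomal protein-coding and lncRNA genes with a mean under 0.1 CPM summed to 179 ± 11.1 CPM in DMSO and 367 ± 40.8 in VE-822, against 246 ± 0.822 and 287 ± 9.90 CPM for 9902 such genes in MP38. Sequencing depth is argued against, since at equal depth the lowest VE-822 library still had 4480 more genes with a count than the highest DMSO library. MP38 RNA is argued against by low genes with no read in any MP38 library, which rose 2.56 times; a first form of this test over all 5941 genes with no MP38 read gave 1.07, as that explanation would have it, and was replaced after it was seen because low genes held 6.48% of that sum. Genomic DNA spread evenly over genes could account for the gain, as the top 5% of low genes carried 30.8% of it, 1.246 times the 24.8% that a gain proportional to length gave in simulated data; the bound set beforehand was 1.5 times, though 30.8% exceeds the highest of 200 simulations, 25.2%. Broad low-level transcription after VE-822 stays open, and so does a trace of MP38 RNA for MMP2, SHANK2, CHL1 and MAP9 (19 to 23 counts in VE-822, 18.5 to 143 CPM in MP38 DMSO), which the genes of that test do not include.

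The remaining values were noted because a test of the difference in response, 92.1 minus MP38, passed its threshold. Among lists, the median difference was 1.24 for p53 targets, 1.95 for replication-dependent histones and 0.56 for cytosolic ribosomal proteins. It was -1.68 for DNA replication and E2F targets, -1.56 for homologous recombination and Fanconi anaemia and -1.11 for the ATR checkpoint. It was -0.57 for cholesterol biosynthesis, -0.55 for hypoxia and glycolysis, -0.45 for melanocyte genes, -0.33 for MAPK output and -0.18 for lysosome and autophagy. With an estimated correlation, p53 targets (adjusted p = 0.0174) and melanocyte genes (adjusted p = 0.0443) passed among these 11 lists, and the other 9 did not (adjusted p = 0.0722 to 0.465).

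Among genes, the fitted difference was positive for HSPA6 (7.42), MMP2 (7.14), SHANK2 (5.81), CHL1 (5.81) and MAP9 (5.63), of which all but HSPA6 are no bounds since a group had no count. It was also positive for H2AC6 (3.36), HSPA1A (3.23), CDKN1A (2.74), LIF (2.53), EGR1 (1.62), CRYAB (1.45), MDM2 (1.252), NT5E (0.47) and ATR (0.26). It was negative for TXNIP (-5.14), ASNSP1 (-4.83), LMX1B (-4.67, no bound for the same reason), CENPE (-3.92), SLC7A11 (-3.79), KIF20A (-3.65) and MKI67 (-3.39). It was negative too for BRCA2 (-2.63), PKMYT1 (-2.59), BRCA1 (-2.35), CHEK1 (-2.20), COL1A1 (-1.53), GLA (-1.26), ECM1 (-0.75), PMEL (-0.51) and MT-CO1 (-0.33). The value of MMP2 was 6.48 without VE-822 library 2 of 92.1. Without DMSO library 3 of 92.1, the value of TXNIP was -4.46, that of SLC7A11 -1.001 and that of ASNSP1 1.05 (adjusted p = 0.55), and ASNSP1 also lost its call without any 1 VE-822 library of 92.1 (adjusted p = 0.0508 to 0.0602). LMX1B lost its call without VE-822 library 3 of MP38 (adjusted p = 0.0525). ATR lost it without any 1 of MP38 DMSO libraries 1 to 3, MP38 VE-822 library 3 (value 0.16) and 92.1 VE-822 libraries 1 to 3 (adjusted p = 0.0505 to 0.105).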

How the results depend on the processing

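The robust fit and the fit of protein-coding genes alone were chosen after seeing the data; they called 11227 and 9115 genes in MP38, 9184 and 7572 in 92.1, and 10157 and 8517 between lines. Of 123 named genes of MP38, 121 were called and 109 kept the call in every setting run. In 92.1 these were 119, 116 and 99, and for the difference between lines 19, 16 and 12. For named genes the settings with an adjusted p of 0.01 and a minimum absolute log2 fold change of 1 were not counted. A setting in which a gene was not tested was not counted as a loss. At 5 CPM, 8019 of the 11194 genes called in MP38 and 5596 of the 9156 called in 92.1 were tested. Of 78 list results 32 were called and 5 kept the call in every setting run. With the replicate number as a block, 10666 genes were called in MP38, 8762 in 92.1 and 9881 between lines; the deviations of equally numbered DMSO and VE-822 libraries correlated at -0.0208 to -0.003 in MP38 and 0.0406 to 0.0822 in 92.1. These lie under the bound of 0.1 set for pairing, but what paired libraries would give was not tested. In 92.1 each DMSO library correlated most with the VE-822 library of its own number, so pairing is not excluded there. With a minimum absolute log2 fold change of 1, counts fell by construction, to 979 higher, 523 lower and 1502 in all in MP38, 1759, 737 and 2496 in 92.1, and 2443, 1240 and 3683 between lines. An adjusted p of 0.01 left 2811 higher and 5887 in all in 92.1. With fewer genes tested, at 5 CPM, 92.1 had 2917 higher, 2805 lower and 5722 in all. On log2(FPKM + 1), which also tested fewer genes, MP38 had 3824 higher, and 92.1 had 2847 higher, 2924 lower and 5771 in all; on log2(FPKM + 0.1) these were 3818, 2832, 2930 and 5762. With no FPKM filter 92.1 had 2757 lower, and the cause was not tested. The correlation between lines was 0.136 with no filter and -0.149 at 5 CPM, and the cause was not tested. Lists called by camera with an estimated correlation were 2 in MP38, 0 in 92.1 and 3 between lines, against 4 in 92.1 at an unadjusted p under 0.05 and, by fry, 19 in MP38 and 18 in 92.1, the tests differing in what they compare. The difference between lines reversed for LMX1B on FPKM (0.14 with log2(FPKM + 1), with and without a filter, and 0.11 with log2(FPKM + 0.1)), where 0 counts in a group weigh less, and for ASNSP1 without 92.1 DMSO library 3, where leaving out 1 library at a time gave -5.40 to 1.05. Leaving out 1 library at a time gave 5262 to 5569 higher, 4850 to 5186 lower and 10112 to 10755 genes in all in MP38 and 11 to 13 lists. In 92.1 it gave 3399 to 6377 higher, 3343 to 6899 lower, 6742 to 13276 in all and 10 to 15 lists, the highest of each without DMSO library 3. Between lines it gave 4431 to 5897 more positive in 92.1, 4473 to 6015 more positive in MP38 and 9259 to 11912 in all, a correlation of 0.0035 to 0.0403 and 1673 to 3398 shared calls in the same direction. Counts thinned to the lowest total of the libraries compared gave 11013 genes in MP38, 9004 in 92.1 and 9382 between lines. In simulated data every missed gene among those changed 4 times was under 1 CPM, where depth was not separated from spread.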

Other observations

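Survival genes moved in both directions in MP38. Of the BCL2 family and caspases, 11 were higher, 7 lower and 4 not past the threshold (12 and 7 adjusted over the list alone; camera adjusted p = 0.0964). The antiapoptotic BCL2A1 rose from 62.2 ± 3.08 to 159 ± 2.88 CPM and MCL1 from 202 ± 4.17 to 329 ± 18.9 CPM, while the proapoptotic BCL2L11 fell from 25.9 ± 0.961 to 14.4 ± 0.865 CPM (SD, n = 3). In 92.1 the list had 3 members higher, 4 lower and 14 not past the threshold (3 and 4 adjusted over the list alone; camera adjusted p = 0.638). The NF-kB and secretory list had 9 members higher, 3 lower and 2 not past the threshold in MP38 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0852, from 0.0459 without DMSO library 2 to 0.893 among genes of at least 5 CPM), and 5, 1 and 7 in 92.1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0734). With all libraries and an estimated correlation the NF-kB and secretory list had an adjusted p = 0.406 in MP38 and 0.206 in 92.1. The cytokine LIF rose in both lines, from 13.1 ± 1.29 to 52.9 ± 9.94 CPM in MP38 and from 0.148 ± 0.0416 to 3.44 ± 0.108 CPM in 92.1. In MP38 the YAP/TAZ targets split, with 9 higher, 8 lower and 1 not past the threshold (9 and 8 adjusted over the list alone; camera adjusted p = 0.212), NT5E rising from 38.3 ± 0.652 to 77.0 ± 0.333 CPM. The extracellular matrix and mesenchymal list had 6 members higher and 10 lower in MP38 (6 and 12 adjusted over the list alone; camera adjusted p = 0.185) and 5 higher and 6 lower in 92.1 (5 and 6 adjusted over the list alone; camera adjusted p = 0.963; median and mean 0.06, test down). The repressor ZEB1 fell from 47.9 ± 1.32 to 25.9 ± 1.13 CPM in MP38, and SNAI2 from 205 ± 3.88 to 129 ± 4.48 CPM in 92.1.

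The type I interferon list in 92.1 had 11 members higher, 3 lower and 12 not past the threshold (12 and 3 adjusted over the list alone; camera adjusted p = 0.126), with TRIM22 up from 0.118 ± 0.0140 to 2.44 ± 0.187 CPM. MHC class I genes in MP38 had 5 higher, 3 lower and 9 not past the threshold (5 and 3 adjusted over the list alone; camera adjusted p = 0.671). The stress list in MP38 had 6 higher, 8 lower and 8 not past the threshold (6 and 9 adjusted over the list alone; camera adjusted p = 0.883; median -0.02, mean 0.06, test up), DDIT3 rising from 67.3 ± 14.5 to 150 ± 18.1 CPM. Markers of class 1 uveal melanoma had 3 higher, 2 lower and 3 not past the threshold in MP38 (3 and 2 adjusted over the list alone; camera adjusted p = 0.959; median -0.07, mean 0.07, test down). In 92.1 they had 2, 2 and 4 (2 and 2 adjusted over the list alone; camera adjusted p = 0.864; median -0.01, mean 0.08, test up). Mitochondrially encoded genes in 92.1 had 4 higher and 9 not past the threshold (4 adjusted over the list alone). The camera adjusted p was 0.0971, from 0.0202 among genes of at least 5 CPM to 0.195 without VE-822 library 1. With all libraries and an estimated correlation it was 0.223. The mitochondrial share of counts in 92.1 was 9.23% ± 0.113 in DMSO and 10.4% ± 0.137 in VE-822 (exact permutation test, two-sided p = 0.1, the smallest possible here).

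In 92.1 the leukocyte list had 4 higher and 2 not past the threshold (4 adjusted over the list alone; camera adjusted p = 0.0529), the fibroblast list 4 and 1 (4 adjusted over the list alone; camera adjusted p = 0.0563) and the endothelial and epithelial list 3 and 2 (3 adjusted over the list alone; camera adjusted p = 0.0604). CD4 was 0.317 ± 0.0462 and 0.931 ± 0.0893 CPM and COL1A1 2.78 ± 0.530 and 4.68 ± 0.380 CPM. Leukocyte markers passed the test without any 1 of the 6 libraries (adjusted p = 0.0196 to 0.0464) and with RLE factors (adjusted p = 0.0423). Fibroblast markers passed it without DMSO library 1 or 2 or VE-822 library 1 or 2 (adjusted p = 0.011 to 0.0369), and the endothelial and epithelial list without any 1 DMSO library or VE-822 library 3 (adjusted p = 0.0187 to 0.0467). More genes passed the filter without a library (23445 to 23905, against 22943 with all), so the tested members of these lists could differ. The mean of the endothelial and epithelial list was 1.27 with all libraries and 2.007 to 2.41 in its passes. With all libraries and an estimated correlation each of the 3 lists had an adjusted p = 0.206, and the passes without a library were not tested with one. Genes at low levels rose in these VE-822 libraries at large, from a sum of 179 to 367 CPM. In MP38 the leukocyte list had 2 higher and 6 not past the threshold (2 adjusted over the list alone; camera adjusted p = 0.808), the fibroblast list 2 and 2 (2 adjusted over the list alone; camera adjusted p = 0.224), and the endothelial and epithelial list 1 higher, 2 lower and 1 not past it (1 and 2 adjusted over the list alone; camera adjusted p = 0.41). COL1A1 was 0.243 ± 0.0430 and 1.21 ± 0.213 CPM there. The 14 lists not called between lines had camera adjusted p-values of 0.063 to 0.892.

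Among long noncoding RNAs, 1009 were higher and 288 lower in 92.1, and 714 higher and 842 lower in MP38. In 92.1 pseudogenes (303 higher, 168 lower) and the sum of genes at low levels (179 to 367 CPM) went the same way. The share of counts in long noncoding RNAs in 92.1 was 2.04% ± 0.261 in DMSO and 2.82% ± 0.0177 in VE-822 (exact permutation test, two-sided p = 0.1, the smallest possible here).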
